A study of Rattus norvegicus with 13 samples.

How the data were processed

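The samples were 13 hepatic RNA samples of time-mated female Sprague Dawley rats, each hybridised to 1 one-colour Affymetrix rat array of 8799 probe sets. The series title gives the tissue, and the labels do not say whether an array holds RNA of 1 animal or of a pool. The day of gestation is not given in the sources used here. The p-values therefore measure only the spread between these samples.

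The deposited values are intensity values, on a linear scale: signals that the authors made with MAS5, as the submitters' processing notes name it; its version is not given in the sources used here. The 2%-trimmed mean signal was 501 on each of 12 arrays, so these had been scaled to a common target, and 133 on TEN-220 replicate 1, which had not been scaled to it. All 13 columns of values were used. Because the trimmed means were not within 10% of their mean, a rule written beforehand called for quantile normalization of all 13 arrays. Signals below the 10th percentile (9.338) were then set to it and the values taken to log2. The 59 control probe sets were left out, and so were the 40% of the other 8740 probe sets with the lowest mean, which left 5244. Of these, 4309 named exactly 1 gene, 245 several and 690 none, as the array's annotation gives them; 4297 of the 4309 were matched to the gene table by their Entrez ID. The 4309 stand for 3130 different genes. The background was taken as the 95th percentile of 19 control probe sets for sequences that rat RNA does not carry, a signal of 44. Where a group lay below it, a lower bound of the fold, or in the interaction of the ratio of 2 folds, is given with that group at 44.

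Group means were fitted with limma 3.58.1 (lmFit on 4 groups, eBayes with a trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment within each of 7 comparisons; a probe set was called at an adjusted p under 0.05. The comparisons were ethanol at 220 kcal (EtOH-220 minus TEN-220), ethanol at 160 kcal (EtOH-160 minus TEN-160), energy without ethanol (TEN-160 minus TEN-220), energy with ethanol (EtOH-160 minus EtOH-220), their interaction (ethanol at 160 kcal minus ethanol at 220 kcal), and the averages of the ethanol and of the energy effects. Changes are differences of mean log2 signal, with the standard error (SE) of the model, and group levels are geometric means of the normalized signal. The number of arrays limits the precision: the median SE of a pairwise change was between 0.238 and 0.254 on the log2 scale.

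Of 34 fixed lists of pathway and cell type genes, 33 had at least 4 measured genes and were tested with limma's camera, with a preset correlation of 0.01 between genes; the neutrophil list had 1. Each gene entered by its brightest probe set. The camera test was repeated with an estimated correlation, and limma's fry, which asks whether a list's genes move on balance in 1 direction, was run beside it. Named genes follow a rule: in a pairwise comparison, the 12 higher and the 12 lower with the largest changes among called probe sets that name 1 gene and whose groups did not overlap, or, where fewer than 10 qualified, the 10 with the smallest p; in the interaction and the averages, the 8 with the smallest adjusted p; 2 to 4 called members of a list, by smallest p; and, called or not, the genes Adh1 (here Adh1c), Cyp2e1, Cat, Aldh2, Aldh1a1, Srebf1, Fasn, Cyp7a1, Igf1, Igfbp1, Pck1, Cpt1a, Cyp4a1, Gsta2, Hmox1 and Afp. Gsta2 had no probe set that named it alone. The comparisons, the lists, this rule, the tests and most alternatives were chosen before the data were examined.

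The procedure was tested on simulated data in which 200 of 5244 probe sets were changed. For ethanol at 220 kcal it recovered 20% of changes of 1.5-fold, 60% of 2-fold, 84% of 4-fold and 86% of 8-fold, with 4 false calls among 129; for ethanol at 160 kcal it recovered 20%, 62%, 88% and 86%, with 6 false calls among 134. None of the unchanged lists was called (0 in each). The simulated probe sets varied independently, so this cannot show how often camera calls unchanged lists whose genes are correlated. The alternatives were other normalizations (median-centred log2 values, values as deposited, trimmed-mean scaling), floors, filters, variance models, array weights, thresholds, a replicate block, fits to the 2 groups alone, other list tests and leaving out arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.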

Results

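Hepatic gene expression was measured in time-mated female Sprague Dawley rats on 4 diets. The control group, TEN-220 (n = 3), received a diet without ethanol at 220 kcal per kg to the power 0.75 per day. EtOH-220 (n = 3) received 12 g ethanol per kg per day at the same energy supply. TEN-160 (n = 3) was an undernourished control group at 160 kcal, and EtOH-160 (n = 4) an undernourished group with 12 g ethanol per kg per day. Of 8740 probe sets other than controls, 5244 were bright enough to be tested.

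The TEN-160 arrays stood apart from the other 10, in rat genes and in the spiked control BioDn-5. The first principal component held 31.1% of the variance, with scores of 31.4, 31.0 and 43.1 in TEN-160 and of −13.6 to −2.98 in the others. The ratio of the signals of the BioDn-5 and BioDn-3 controls, 2 probe sets for the ends of a bacterial transcript, was 0.426, 0.422 and 0.497 on the TEN-160 arrays and 0.132 to 0.210 on the others. Rat RNA does not carry this sequence. The scaled signal of BioDn-5 was 2197 to 2353 on the TEN-160 arrays and 588 to 1041 on the others. Those of BioDn-3 and of the BioB, BioC and CreX control probe sets ending in _at overlapped. The GAPDH 3'/5' signal ratio, a sign of RNA quality, was 1.026 to 1.242 in TEN-160 and 1.038 to 1.47 in EtOH-220. It was 1.525 to 2.323 in TEN-220 and 1.505 to 1.726 in EtOH-160. The groups of each pairwise comparison therefore did not overlap in this ratio, whereas their actin 3'/5' ratios did. All comparisons that use TEN-160 hold these differences between arrays as well as the diet. The pairwise comparisons without TEN-160 hold the difference in the GAPDH ratio.

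**Figure D1:**
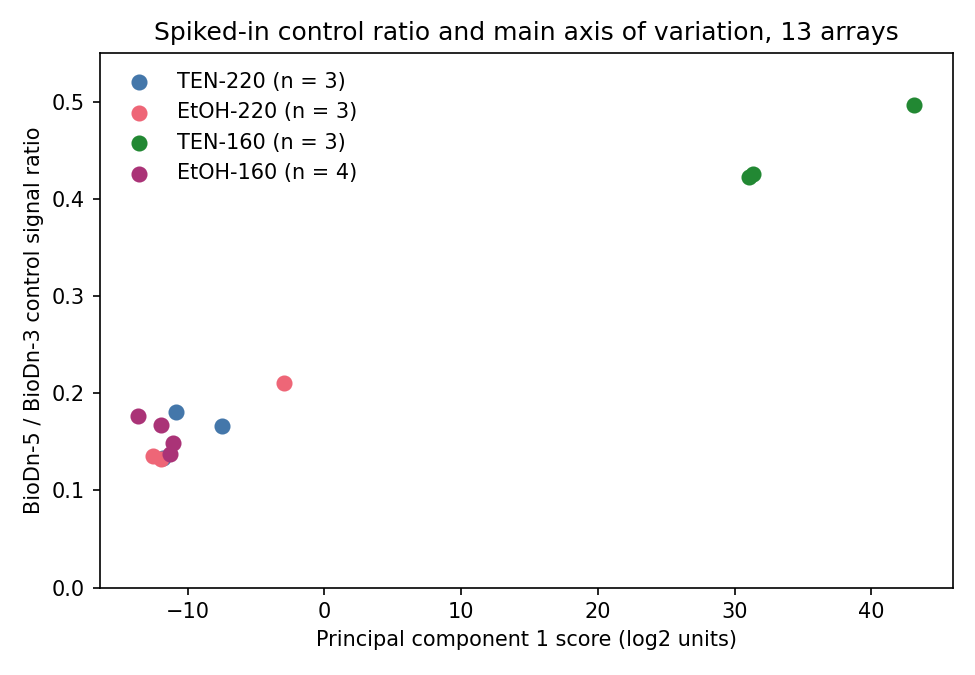
Each point is 1 of the 13 arrays, coloured by group; the x axis is the score on the first principal component (log2 units) and the y axis the ratio of the BioDn-5 and BioDn-3 control signals (no unit). The 3 TEN-160 arrays lie at ratios of 0.422 to 0.497, above the 0.132 to 0.210 of the other 10.

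The effect of ethanol on normally fed rats was asked by EtOH-220 against TEN-220. Camera called 7 lists of genes for hepatic metabolism higher, by small amounts, but 0 with an estimated correlation between genes and 0 with fry, and single genes rarely passed. In the list of cytochrome P450 families CYP1 to CYP3, which hold enzymes for drugs and steroids, 22 of 25 measured genes had positive changes, with a median of 0.22 on the log2 scale (camera adjusted p = 0.000258, and 0.352 with an estimated correlation). The 33 genes of fatty acid oxidation and PPAR-alpha targets had a median change of 0.16 (adjusted p = 0.00132 and 0.352), and the 11 markers of periportal hepatocytes, the cells near the portal vein, a median of 0.28 (adjusted p = 0.00146 and 0.352). In the methionine cycle and one-carbon metabolism, 14 of 17 genes had positive changes, with a median of 0.14 (adjusted p = 0.0061 and 0.352). The lists of female-biased and of male-biased liver genes rose as well (medians of 0.20 and 0.35, camera adjusted p = 0.0101 and 0.0323, and 0.352 for both with the estimated correlation), as did the list of urea cycle and amino acid catabolism (median of 0.12, adjusted p = 0.0323 and 0.561). The urea cycle call was also lost with no filter and under trimmed-mean scaling, and the male-biased call with the mean of a gene's probe sets and without EtOH-220 replicate 1. These 7 lists are not separate results, since they share members. As written, both sex-biased lists hold genes of the P450 list, and the periportal list holds genes of the urea cycle list. No member of these lists was called over all genes. Adjusted over the list alone, 3 genes of the methionine cycle, 2 of fatty acid oxidation, 2 of the periportal list and 1 of the male-biased list were higher, and 0 of the P450, female-biased and urea cycle lists.

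The 1 probe set called in this comparison was for Fam111a, which encodes a serine protease of DNA replication. Its level fell from 700 in TEN-220 to 55.4 in EtOH-220, by 3.66 on the log2 scale (SE 0.522, adjusted p = 0.035). Without EtOH-220 replicate 1 it fell by 4.46, with the other 2 arrays at 31.7, below the background of 44, so the fold is then at least 15.9. The 9 genes with the next smallest p were not called, although the groups did not overlap for any of them. Among these, the methionine cycle genes Bhmt and Cth had changes of 1.00 and 1.07 (SE 0.172 and 0.178, adjusted p = 0.0504 for both). Bhmt makes methionine from betaine, and Cth makes cysteine from cystathionine. Hmox1, the inducible haem oxygenase, had a change of −1.97 and Inhbe, an inhibin subunit, of −1.02 (adjusted p = 0.0504 for both). The others were Apob (2.16), Oaz2 (1.16), Map3k12 (1.77), Ank3 (1.51) and Cebpb (−0.75), at adjusted p between 0.0645 and 0.0897. Only 4 of the 5 probe sets of Apob had the same sign.

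An unadjusted p under 0.05 was reached by 524 probe sets, against 262.2 by chance, and the groups did not overlap for 17.8%, against 10% by chance. The call of Fam111a ended, with a count of 0, without TEN-220 replicate 1 or 2, EtOH-220 replicate 3 or EtOH-160 replicate 1, 2 or 3, with no filter, without a variance trend and with only the 2 groups; the count was 12 without EtOH-220 replicate 2 and 58 with the values as deposited.

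The effect of a lower energy supply without ethanol was asked by TEN-160 against TEN-220. Genes for making fat were lower in the undernourished rats, while genes of the fasting response went both ways. In the lipogenesis list 6 of 14 measured genes fell and 0 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.0099). With an estimated correlation the adjusted p was 0.908. Pnpla3, a lipase-like protein of fat droplets, fell by 3.83 (SE 0.527, adjusted p = 0.000449), from a level of 4618 to 324. Both probe sets of Fasn, the fatty acid synthase, fell, by 2.83 and 2.21 (SE 0.357 and 0.307). Acly, which supplies acetyl-CoA to this synthesis, fell by 1.96, the desaturase Scd by 1.56 and Srebf1, a transcription factor for these genes, by 1.56 (SE 0.318, 0.239 and 0.326).

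Igfbp1, a binding protein of insulin-like growth factors, rose from 187 to 1678, by 3.16 (SE 0.587, adjusted p = 0.00277). Pck1, the gluconeogenic PEP carboxykinase, rose by 2.48 (SE 0.632, adjusted p = 0.0163), and Cpt1a, which brings fatty acids into mitochondria, by 2.07 (SE 0.314, adjusted p = 8e-04). Their lists did not move in 1 direction. In gluconeogenesis and the fasting response 3 of 17 genes rose and 4 fell, among them Cebpb (−1.16; adjusted p of the list 0.971). In fatty acid oxidation 3 of 33 rose and 6 fell, among them Hadh (−2.21, at least 2.92-fold; adjusted p of the list 0.971). In the growth hormone, insulin and IGF list 3 of 19 rose and 2 fell: Socs2, an inhibitor of growth hormone signalling, rose by 1.68, at least 2.83-fold, while Igfbp3 and Igfals, partners of circulating IGF-1, fell by 1.47 and 1.01 (SE 0.349, 0.187 and 0.18; adjusted p of the list 0.971). Of the bile acid list 4 of 15 rose and 1 fell, and the camera adjusted p of the list was 0.277. Slc10a1, the bile salt uptake carrier, rose by 1.18 and Slco1a4 by 1.32 (SE 0.178 and 0.293). Besides lipogenesis, fry called the bile acid list and the circadian clock list, which camera did not call. In the heat shock list 4 of 9 fell and 0 rose, led by Hsph1 (−1.17, SE 0.259; adjusted p of the list 0.277).

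In all, 411 probe sets were higher and 521 lower at 160 kcal. By size of change the higher ones, besides Igfbp1 and Pck1, were Kctd13 (4.25), the clock repressor Nr1d2 (2.94, at least 3.98-fold), Pzp (2.82), Rapgef4 (2.59), Serpina7 (2.54), Bet1 (2.45), Cyb5a (2.40), Evi5 (2.35), Adra2a (2.31; 2.91 without TEN-160 replicate 3) and Dcn (2.16, at least 2.31-fold). The lower ones, besides Pnpla3 and Fasn, were Ptms (−4.59), Pdpk1 (−3.92), Idh1 (−3.53), Mgll (−3.15), Slc4a2 (−2.76), Sirt2 (−2.76), Cited2 (−2.74), the fetal albumin-like protein Afp (−2.69), Dusp1 (−2.51) and Map2k5 (−2.51), at adjusted p between 5.84e-06 and 0.00327. Ptms, Pdpk1, Idh1, Cited2, Afp and Map2k5 were below the background of 44 in TEN-160, so their folds are at least 9.48, 3.21, 5.85, 3.53, 3.53 and 2.26. For Idh1, Cited2 and Kctd13 another probe set of the same gene had the opposite sign. Ptms, Pzp, Cyb5a and Adra2a had another probe set with the same sign but changes of only −0.37, 0.29, 0.34 and 0.30. The same held for Dcn, Dusp1 and Map2k5, at 0.29, −0.24 and −0.36. The other probe sets of Slc4a2 and Afp had −0.94 and −1.09.

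Groups did not overlap for 36.5% of the probe sets, against 10% by chance. The count of 932 was 543 without TEN-220 replicate 1, 546 without TEN-220 replicate 2 and 346 with the values as deposited, where replicate 1 stays unscaled. The call of Pck1 ended without TEN-220 replicate 1 or 2 or TEN-160 replicate 3, at an adjusted p of up to 0.0774 and changes of 1.83 to 3.21 over all single arrays left out, and that of Dcn without any of 5 single arrays, at up to 0.136.

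**Figure D2:**
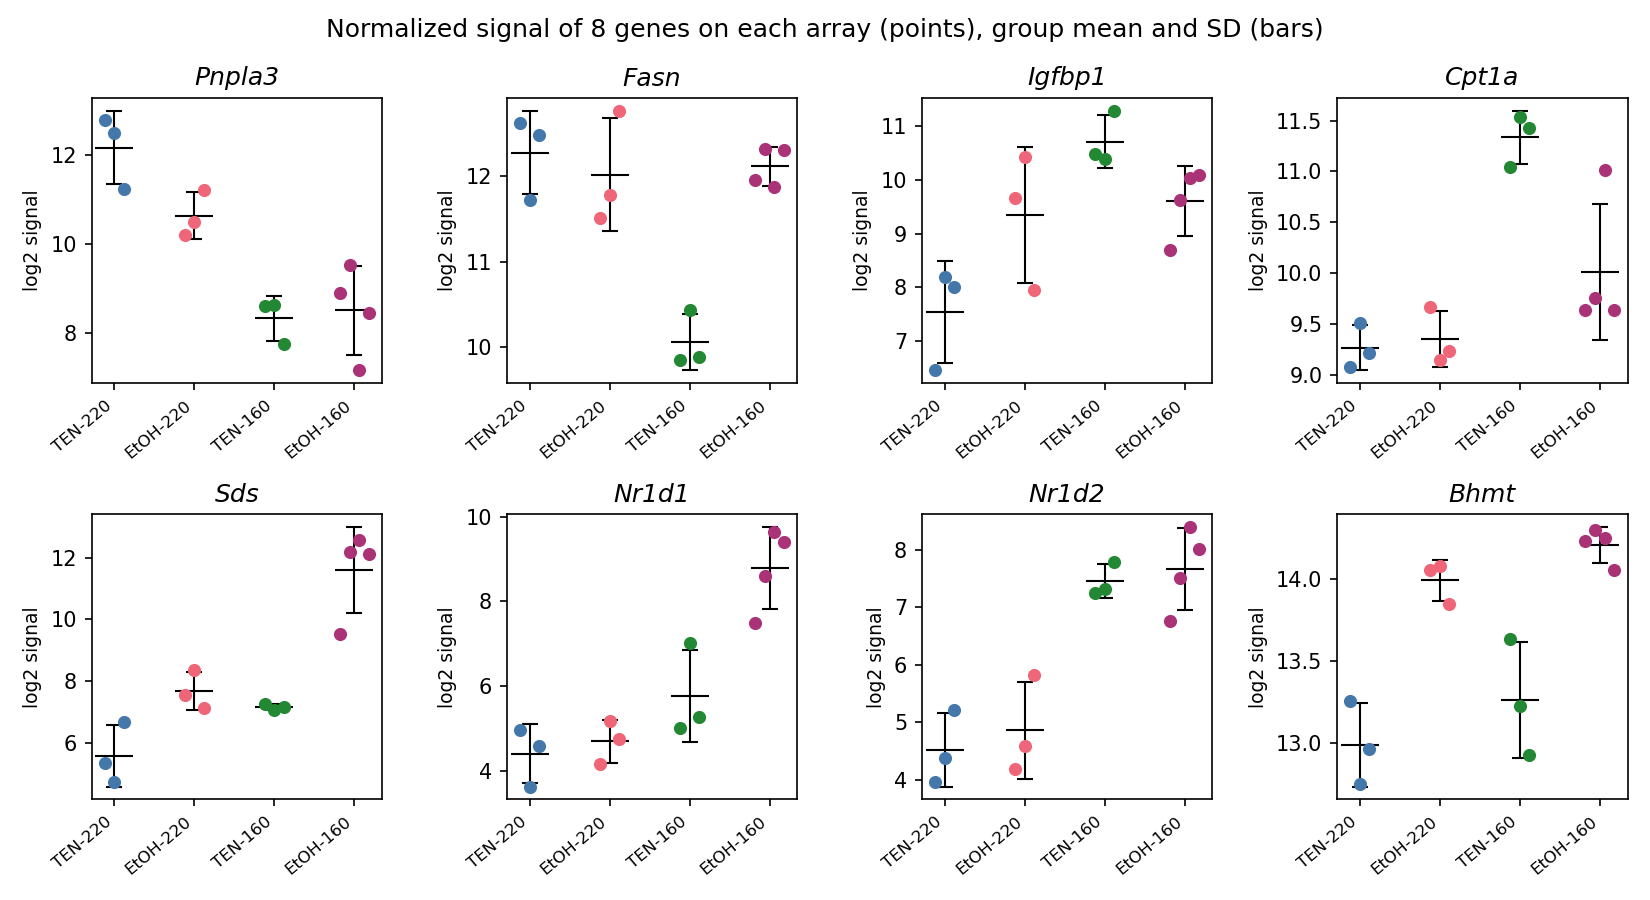
Each panel shows the log2 normalized signal of 1 gene on each of the 13 arrays (points) by diet group, with the group mean (long line) and SD (bars; n = 3, 3, 3 and 4). Pnpla3 is lower and Nr1d2 higher in both 160 kcal groups, Bhmt is higher in both ethanol groups, and the mean of Fasn is lowest in TEN-160.

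The effect of ethanol on undernourished rats was asked by EtOH-160 against TEN-160. Genes of amino acid breakdown, glucose production, fat synthesis and methionine metabolism were higher with ethanol, and 3 MHC class II genes among the Kupffer cell markers were lower. In the list of urea cycle and amino acid catabolism 13 of 29 measured genes rose and 0 fell (camera adjusted p = 9.57e-05, and 0.328 with an estimated correlation). This holds for the brightest probe set of each gene. Oat, a member, had −0.25 on that probe set, not called, but fell by 2.32 on its other one, which was called. Sds, the serine dehydratase, rose from 142 to 3094, by 4.44 on the log2 scale (SE 0.615, adjusted p = 0.000405), and by 5.12 without EtOH-160 replicate 1. The alanine aminotransferase Gpt rose by 2.13, Asl of the urea cycle by 1.39 and Haao of tryptophan breakdown by 1.14 (SE 0.286, 0.192 and 0.126). In gluconeogenesis and the fasting response 9 of 17 rose and 1 fell (adjusted p = 0.000729, and 0.155 under that correlation); Slc37a4, which carries glucose 6-phosphate, rose by 1.67 and the glycerol channel Aqp9 by 1.00 (SE 0.185 and 0.187). Of the markers of periportal hepatocytes 6 of 11 rose and 0 fell (adjusted p = 0.000729 and 0.155), with Arg1 up by 0.86 and Gls2 by 1.25 (SE 0.143 and 0.23). These 3 lists share members, Sds among them. In lipogenesis 5 of 14 rose and 1 fell (adjusted p = 0.0202 and 0.583): Fasn rose by 2.05, Scd by 1.35 and the citrate carrier Slc25a1 by 1.25, and the elongase Elovl5 fell by 0.68 (SE 0.287, 0.224, 0.254 and 0.139). In the methionine cycle and one-carbon metabolism 6 of 17 rose and 1 fell (adjusted p = 0.0202 and 0.328), with Gnmt at 1.51, Ahcy at 1.09 and Bhmt at 0.95 (SE 0.236, 0.2 and 0.161).

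Of 9 markers of Kupffer cells and macrophages 3 fell and 0 rose (adjusted p = 0.015; 0.669 with an estimated correlation): RT1-Ba by 1.42, RT1-Bb by 0.80 and RT1-Da by 0.65, all MHC class II chains (SE 0.279, 0.248 and 0.148). This call was lost under trimmed-mean scaling. Adjusted over the list alone, the genes higher and lower were 14 and 1 for the urea cycle, 12 and 2 for gluconeogenesis, 6 and 0 for periportal cells, 6 and 1 for lipogenesis, 6 and 1 for the methionine cycle and 0 and 4 for Kupffer cells. The P450 list was not called (adjusted p = 0.489), but 8 of its 25 genes rose and 2 fell. Among them Cyp3a23-3a1 rose by 1.84, Cyp2a1 by 0.97 and Cyp2d2 by 0.62, and the female-specific Cyp2c12 fell by 0.77 (SE 0.31, 0.165, 0.0915 and 0.133). Cyp2b2, known for its induction by phenobarbital, rose from 779 to 5543, by 2.83 (SE 0.55, adjusted p = 0.00304). Cyp4a1, the fatty acid hydroxylase, rose by 1.16 (SE 0.226, adjusted p = 0.0031), while Cpt1a fell by 1.33 (SE 0.294, adjusted p = 0.00662).

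In all, 622 probe sets were higher and 546 lower with ethanol at 160 kcal. Besides Sds and Cyp2b2 the largest rises were those of Ptms (4.18), Pdpk1 (4.06), Itga7 (3.37), Idh1 (3.02), the clock repressor Nr1d1 (3.01, 3.66 or at least 9.99-fold without TEN-160 replicate 2, and 0.98 on its other probe set), Alkbh7 (2.96), Cited2 (2.93), Hpd (2.76), Sirt2 (2.67) and Tle5 (2.66). In 7 of them the TEN-160 level was below the background, so the folds are at least 7.15 for Ptms, 3.53 for Pdpk1, 3.85 for Itga7, 4.09 for Idh1, 5.35 for Alkbh7, 4.02 for Cited2 and 5.16 for Hpd. The largest falls were those of Kctd13 (−3.70), the acute phase protein Lcn2 (−2.78), Pzp (−2.59), Ces1d (−2.42), the growth hormone receptor Ghr (−2.36), Oat (−2.32), Myl12b (−2.27), Evi5 (−2.24), Ptbp3 (−2.21), the clock activator Bmal1 (−2.19), Bet1 (−2.17) and the receptor Igf2r (−2.11), at adjusted p between 6.04e-05 and 0.00739. The naming rule admits only genes whose groups did not overlap. For some of them TEN-160 alone stood apart. In the order TEN-220, EtOH-220, TEN-160 and EtOH-160, the levels of Oat on this probe set were 771, 676, 3371 and 677. Those of Evi5 were 65.3, 65.5, 333 and 70.4. For Sds, in contrast, EtOH-160 stood apart (47.65, 204, 142 and 3094). TEN-160 lay wholly above or below the other 10 arrays for 787 of the 5244 probe sets, against 36.7 by chance. For Idh1, Cited2, Kctd13 and Tle5 another probe set of the gene had the opposite sign. Ptms, Pzp, Oat and Myl12b had another probe set with the same sign but changes of only 0.21, −0.50, −0.25 and −0.14. In Itga7, Hpd, Ghr and Bmal1 the smallest change was 0.79, 0.56, −0.76 and −1.11. The other probe sets of Sds and Cyp2b2 had 2.08 and 2.30.

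Groups did not overlap for 31.1% of the 5244 probe sets, against 5.71% by chance, and the count of 1168 was 107 with the values as deposited. Because both comparisons use the TEN-160 arrays, the changes across probe sets were correlated with those of energy without ethanol at r = −0.776, where simulated data without any change gave −0.536. Their covariance was −0.364, against −0.0491 in the simulations. Of the probe sets called in both, 641 had opposite signs, 1 was higher in both and 1 lower in both.

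The effect of energy supply on ethanol-fed rats was asked by EtOH-160 against EtOH-220, a comparison without the TEN-160 arrays. Undernourished rats had higher levels of genes for amino acid breakdown and of clock repressors, and lower levels of cytoskeletal actins. Chance could not be excluded for the number of calls, since 2 of 35 splits of these arrays gave as many or more. Sds rose from 204 to 3094, by 3.92 on the log2 scale (SE 0.615, adjusted p = 0.0159; 4.60 without EtOH-160 replicate 1), and Asl from 1252 to 3115, by 1.32 (SE 0.192, adjusted p = 0.00963). Nr1d1 rose by 4.08, at least 9.99-fold, on 1 probe set and by 1.61 on the other, brighter one (SE 0.574 and 0.296, adjusted p = 0.00963 and 0.0414), and Nr1d2 by 2.81, at least 4.63-fold (SE 0.458, adjusted p = 0.0159). Klf9, a transcription factor induced by glucocorticoids and thyroid hormone, rose by 1.30 (SE 0.208, adjusted p = 0.0159). Actb and Actg1, the cytoplasmic actins, fell by 0.79 and 1.41 (SE 0.112 and 0.207, adjusted p = 0.00963 for both). Next by p, and not called, were Pros1 (0.78, adjusted p = 0.0512), Slc37a4 (1.01, 0.0547) and Gnmt (1.25, 0.0561).

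As lists, the urea cycle and amino acid catabolism (25 of 29 genes with positive changes, median 0.31, camera adjusted p = 1.03e-06, and 0.166 with an estimated correlation), gluconeogenesis (median 0.31, adjusted p = 3.07e-05 and 0.066), periportal hepatocytes (median 0.74, adjusted p = 9.82e-05 and 0.0858) and the circadian clock (median 0.40, adjusted p = 0.0293 and 0.166) rose. Called members were Asl and Sds in the urea cycle and periportal lists, Sds in gluconeogenesis, and Nr1d1 and Nr1d2 among 7 clock genes. The heat shock list (8 of 9 negative, median −0.45, adjusted p = 0.000356 and 0.284), the Kupffer list (8 of 9 negative, median −0.26, adjusted p = 0.0157 and 0.498) and proteasome subunits (20 of 24 negative, median −0.16, adjusted p = 0.0186 and 0.609) fell, with 0 called members. The clock call was lost with no filter, without EtOH-220 replicate 1 and without the TEN-160 arrays, the Kupffer call with no filter and the proteasome call with the replicate number as a block; fry called the 4 lists that rose and 0 that fell. Adjusted over the list alone, 8 urea cycle, 4 gluconeogenesis, 6 periportal and 3 clock genes were higher, 2 heat shock genes were lower, and 0 in the Kupffer and proteasome lists.

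There were 11 probe sets called higher and 4 lower. The count of 15 was 0 without EtOH-160 replicate 3 or 4, 4, 26 and 6 without EtOH-220 replicates 1, 2 and 3, 5 without EtOH-160 replicate 2 and 52 without EtOH-160 replicate 1; 12 were called without the TEN-160 arrays, 6 with only the 2 groups and 0 with no filter. With the replicate number as a block 2 were called, Asl and Nr1d2, so the calls of Sds, Nr1d1, Klf9 and both actins ended. Without EtOH-220 replicate 1 the calls of Sds, Asl, Nr1d2, Klf9 and Nr1d1 on the first probe set ended, without EtOH-220 replicate 3 those of Sds, Klf9 and Actg1, and without EtOH-160 replicate 2 those of Sds, Klf9 and Nr1d2. Of the 15, 93.3% had the same sign in energy without ethanol, where 4 were also called higher, 3 lower and 1 in the opposite direction. Across all probe sets the energy effects with and without ethanol were almost uncorrelated (r = 0.036), as were the ethanol effects at 220 and 160 kcal (r = 0.031). Genes are not independent replicates. The median absolute change was 0.208 for energy with ethanol, against a median SE of 0.238. It was 0.215 for ethanol at 220 kcal, against 0.254. The other comparison of each pair uses TEN-160. An r near 0 therefore cannot show that the effects are unrelated.

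Whether the effect of ethanol depended on energy supply was tested by the interaction, which called 374 probe sets, 212 of them positive. It uses the TEN-160 arrays, so an array artifact of that group cannot be told apart from such a dependence. TEN-160 alone stood apart for Sirt2, with levels of 678 in TEN-220, 632 in EtOH-220, 100 in TEN-160 and 641 in EtOH-160. The levels of Sdc4 were 3267, 3213, 1187 and 3779 in the same order. Among the 374 was Fasn, which ethanol changed by −0.25 at 220 kcal and by 2.05 at 160 kcal, a difference of 2.31 (SE 0.421, adjusted p = 0.00726). The group levels were 4949 in TEN-220, 4150 in EtOH-220, 1068 in TEN-160 and 4432 in EtOH-160. For Igfbp1 the difference was −2.90 (SE 0.804, adjusted p = 0.0451), with levels of 187, 652, 1678 and 783 in the same order; this call ended without any of 12 of the 13 arrays, at an adjusted p of up to 0.112, and the difference was −3.60 without EtOH-220 replicate 3. For Hmox1 it was 1.74 (SE 0.424, adjusted p = 0.0283), with levels of 1590, 620, 921 and 1196; this call ended without any of 5 of the 13 arrays, at an adjusted p of up to 0.0658. The 8 with the smallest p were Pdpk1 (4.22, adjusted p = 0.000124), Sdc4 (1.70), Tkfc (1.75), Ptpn21 (1.89), Hpd (2.76), Ptms (4.91), Sirt2 (2.78) and Cyb5a (−2.66), at adjusted p of at most 0.00206. Because TEN-160 was below the background for Pdpk1, Hpd and Ptms, their differences amount to ratios of folds of at least 3.96, 5.16 and 11.9. Another probe set of Sdc4 had the opposite sign (−0.10). Other probe sets of Hpd, Ptms and Cyb5a had the same sign but differences as small as 0.82, 0.84 and −0.40. The urea cycle list had a positive interaction (median 0.48, adjusted p = 0.028; 0.931 with an estimated correlation). Without TEN-220 replicate 1 or 2 the count was 132 or 180, and with the values as deposited it was 65.

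Averaged over both energy levels, ethanol raised 246 probe sets and lowered 254. Bhmt rose by 0.97 (SE 0.118, adjusted p = 0.00136), with levels of 8143 in TEN-220, 16310 in EtOH-220, 9834 in TEN-160 and 18940 in EtOH-160. Others with the smallest p were Ank3 (1.60, at least 2.97-fold), Haao (0.71), Tnk2 (1.26), Sdc4 (0.82), Pdpk1 (1.95, at least 1.78-fold), H2az1 (−1.04) and Arf4 (−0.65). At 220 kcal alone, a comparison that does not use TEN-160, the changes of these 7 were 1.51, 0.28, 0.14, −0.02, −0.16, −0.47 and −0.22. The averages of Sdc4 and Pdpk1 therefore rest on the change at 160 kcal, and those of Tnk2, Haao, H2az1 and Arf4 mostly do. For H2az1 the levels were 584 in TEN-220, 421 in EtOH-220, 1459 in TEN-160 and 479 in EtOH-160. The change of Bhmt was 1.00 at 220 kcal and 0.95 at 160 kcal. Lists that rose were the urea cycle (adjusted p = 1.12e-05), periportal hepatocytes (1.12e-05), gluconeogenesis (7.45e-05), methionine cycle (0.000589), fatty acid oxidation (0.00673), P450 (0.0126) and lipogenesis (0.0329), and those of Kupffer cells (0.0126), proteasome subunits (0.024) and endoplasmic reticulum stress (0.0422) fell. With an estimated correlation the periportal and gluconeogenesis calls held (adjusted p = 0.0474 for both), and the adjusted p of the others was 0.106 to 0.673. In the pairwise comparisons camera called lipogenesis, gluconeogenesis and Kupffer cells at 160 kcal only, where TEN-160 is used. Fatty acid oxidation and P450 were called at 220 kcal only, and proteasome subunits and endoplasmic reticulum stress at neither.

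Averaged over both diets, the lower energy supply raised 222 probe sets and lowered 251. Plin2, a coat protein of fat droplets, fell by 1.39 (SE 0.131, adjusted p = 0.00028), from 9605 to 2312 without ethanol and from 7391 to 4500 with it. Pnpla3 fell by 2.98 and Mgll, the monoglyceride lipase, by 1.94 (SE 0.361 and 0.246). Nr1d2 rose by 2.87, at least 4.29-fold, and Ugt2b35 by 1.28, and Actg1, Pdpk1 and Ormdl3 fell by 1.32, 1.81 (at least 1.61-fold) and 0.79, at adjusted p of at most 0.000748. The comparison of the ethanol-fed rats alone does not use TEN-160. Its changes were −2.13 for Pnpla3, −0.73 for Mgll, 2.81 for Nr1d2, 0.54 for Ugt2b35, −1.41 for Actg1, 0.30 for Pdpk1 and −0.08 for Ormdl3. The averages of Pdpk1 and Ormdl3 therefore rest on the change without ethanol, and those of Mgll and Ugt2b35 mostly do. The lipogenesis and heat shock lists fell (adjusted p = 0.00165 and 0.00335), and the bile acid and periportal lists rose (adjusted p = 0.0466 for both). Under an estimated correlation these were 0.374 for lipogenesis, 0.403 for heat shock, 0.374 for bile acids and 0.398 for periportal cells. The counts of the averages were 103 for ethanol and 64 for energy with the values as deposited, 296 and 284 without TEN-220 replicate 1, 300 and 301 without TEN-220 replicate 2, and 314 for ethanol without EtOH-220 replicate 3.

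The enzymes that oxidise ethanol and acetaldehyde did not move as a list in any pairwise comparison (adjusted p = 0.524 and 0.83 for ethanol at 220 and 160 kcal, 0.993 and 0.663 for energy without and with ethanol). Adh1c, the main alcohol dehydrogenase, had levels of 22930 in TEN-220, 17710 in EtOH-220, 11880 in TEN-160 and 13840 in EtOH-160, and fell with energy without ethanol by 0.95 (SE 0.13, adjusted p = 0.000429), though by only 0.11 with the values as deposited (adjusted p = 0.884). The other probe set of Adh1c fell by only 0.29 in that comparison and was not called. With ethanol at 160 kcal the 2 probe sets went opposite ways, by 0.22 on the brightest and −0.52 on the other. With ethanol averaged over both energy levels the other probe set was called lower, by 0.43. Cyp2e1, the ethanol-inducible P450, had levels of 24640, 24420, 17070 and 23470 in the same order of groups. It rose by 0.46 with ethanol at 160 kcal and fell by 0.53 with energy without ethanol (adjusted p = 0.0413 and 0.0356), but with the values as deposited the latter change was 0.31, of the opposite sign (adjusted p = 0.665). The values as deposited keep TEN-220 replicate 1 unscaled, which lowers TEN-220 signals in general, so neither shift is specific to Adh1c or Cyp2e1. Both calls of Cyp2e1 ended without some single arrays, 10 of 13 for the former and 5 of 13 for the latter, at an adjusted p of up to 0.186 and 0.132. Aldh1a1, a retinal dehydrogenase, rose by 1.08 with ethanol at 160 kcal (SE 0.243, adjusted p = 0.0073). Catalase (Cat) had levels of 2938, 3824, 6219 and 3152 and the mitochondrial Aldh2 of 4828, 3328, 3136 and 4373, with no call in any pairwise comparison. The brightest probe set of Igf1 (7448, 6716, 7576 and 7910) and that of Cyp7a1, the rate-limiting enzyme of bile acid synthesis (388, 820, 675 and 656), were not called either. Of the 5 probe sets of Igf1, 1 was called, higher by 1.33 with energy without ethanol and lower by 1.26 with ethanol at 160 kcal (adjusted p = 0.0132 and 0.0102). A second probe set of Afp had levels of 325, 316, 153 and 327.

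**Figure D3:**
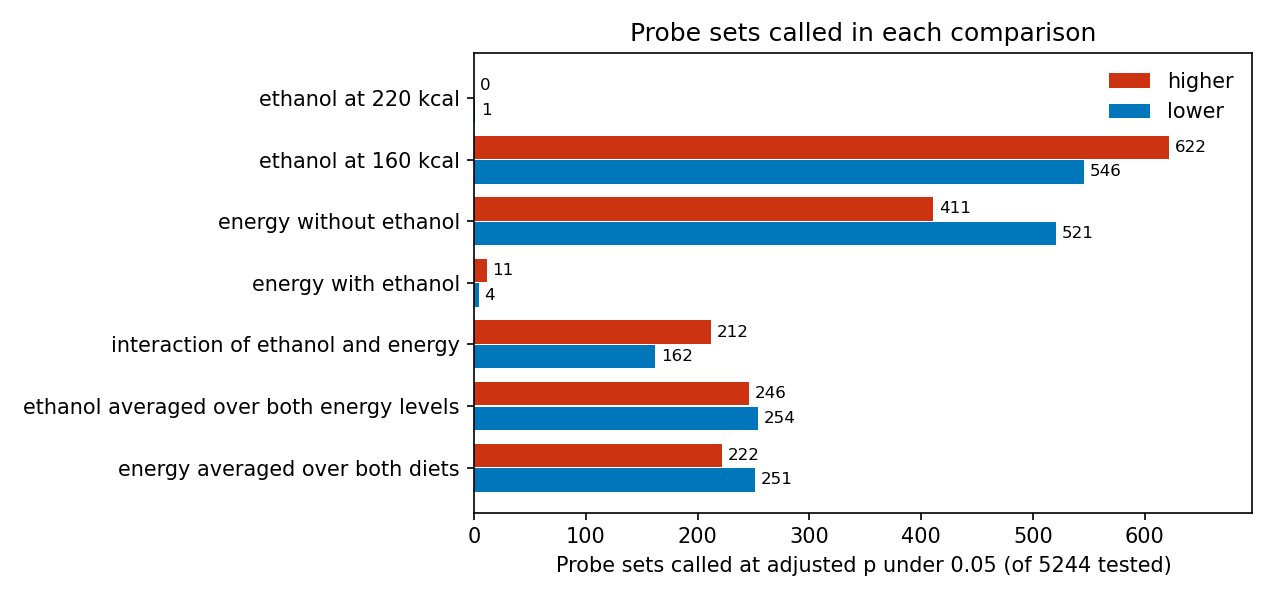
Bars give the number of probe sets called higher and lower (x axis, adjusted p under 0.05, of 5244 tested) in each of the 7 comparisons. The comparisons without the TEN-160 arrays have 1 and 15 calls, and the pairwise ones with them 1168 and 932.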

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

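The tests of controls and of the top 200 genes in TEN-160, of the clock and of RNA quality were chosen only after the result was seen; those of second probe sets of called genes, of cell types and of other splits of the arrays were not.

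The 3 TEN-160 arrays stood apart from the other 10, with BioDn-5 over BioDn-3 control ratios of 0.426, 0.422 and 0.497, and the comparisons that use them gave most calls. A probe-set artifact as the whole cause is argued against by second probe sets from another sequence of the same gene: these went the same way as the called one in 65.5% of 261 genes for ethanol at 160 kcal (95% exact interval 59.4 to 71.3; 45 also called, median change 0.227 against 1.03) and in 60.6% of 226 for energy without ethanol (53.9 to 67.0; 30 also called, 0.14 against 1.01). A difference in hybridisation or arrays stays open, confounded with the group: of 31 bacterial and phage control probe sets other than these 2, 4 put TEN-160 wholly above or below the others, against at most 3 for any other set of 3 arrays. Whether an artifact is part of the changes stays open too: among the 200 genes with the smallest p, second probe sets went the same way in 67.9% and 66.7%, against 87.0% for energy with ethanol (Fisher's exact p = 0.0139 and 0.00883) but 75.0% for ethanol at 220 kcal (0.379 and 0.298), neither of which uses these arrays. The undernutrition itself stays open as well, untested, because these arrays are that group. An artifact in the RNA would pass the test of second probe sets and stays open too. The GAPDH 3'/5' ratios of TEN-160, 1.026 to 1.242, lay wholly below those of TEN-220 (1.525 to 2.323) and EtOH-160 (1.505 to 1.726). They overlapped those of EtOH-220 (1.038 to 1.47), and the actin 3'/5' ratios of all groups overlapped. Whether this difference in the RNA gave any of the calls was not tested.

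Nr1d1 and Nr1d2 were higher in EtOH-160 than in EtOH-220, and a candidate explanation is a shift of the clock phase at the time of sampling, which the labels do not give. A shift would raise Nr1d1, Nr1d2, Dbp and Tef and lower Bmal1; on the brightest probe set of each, the first had changes of 1.61, 2.81 (at least 4.63-fold), 3.99 (at least 9.72-fold) and 0.40 (Dbp and Tef not called, adjusted p = 0.0871 and 0.506; the other probe set of Nr1d1 had 4.08) and Bmal1 of −1.43 (SE 0.683, adjusted p = 0.466), with −1.36 on its other probe set (SE 0.392, adjusted p = 0.173). With 1 measured gene on the opposite side, a phase shift cannot be told apart from another effect of diet on the repressors.

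EtOH-220 replicate 1 stood apart from the other EtOH-220 arrays, with a score of −35.6 on the third principal component, where the other 12 arrays lay between −6.68 and 12.3. Lower RNA quality is argued against by its GAPDH 3'/5' signal ratio of 1.04, below the median of 1.5 over the 13 arrays. An excess of cells of another type on this array is argued against by the marker lists. The highest median difference to the other EtOH-220 arrays was 0.161 on the log2 scale, for lymphocytes. The neutrophil list had 1 measured gene, at 0.77. Kupffer and exocrine pancreas markers were at −0.55 and −0.90, with 0 of 9 and 0 of 6 genes higher. Fewer such cells than on the other EtOH-220 arrays stays open, since the test asked only for higher markers. No biological explanation was tested, since the design gives none for a single array.

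Other splits of the same arrays tested whether chance could give the counts. For ethanol at 160 kcal 1 of the 35 splits, the real one, gave 1168 or more, and the highest other gave 23. That share of 0.0286 is the smallest that 35 splits can give, so it argues against chance without excluding it. For the interaction the count was 374, against 186 in the highest other split. The counts were 500 against 433 for ethanol averaged over both energy levels and 473 against 402 for energy averaged over both diets. In each of these, 1 of 100 splits, the real one, was as large. These splits cannot show that ethanol at 160 kcal, the interaction or the averaged effect itself gave the counts. Other splits also break up a difference of the TEN-160 arrays alone, which all of these counts use. For energy with ethanol chance could not be excluded, since 2 of the 35 splits gave 15 or more and the highest other gave 40. For ethanol at 220 kcal (1, with 2 in the highest other split and 3 of 10 splits as large) and energy without ethanol (932, with 1 in the highest other and 1 of 10 as large) the 10 splits are too few for a share under 0.05.

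The interaction test called a difference in the effect of ethanol between the energy levels for 374 probe sets. It uses the TEN-160 arrays, so an array artifact of that group cannot be told apart from a dependence on energy supply. The differences were 4.22 for Pdpk1, 1.70 for Sdc4, 1.75 for Tkfc, 1.89 for Ptpn21, 2.76 for Hpd, 4.91 for Ptms, −2.66 for Cyb5a, 2.78 for Sirt2, −2.90 for Igfbp1, 1.74 for Hmox1 and 2.31 for Fasn, and the median for the urea cycle list was 0.481. With TEN-160 below the background, those of Pdpk1, Hpd and Ptms amount to ratios of folds of at least 3.96, 5.16 and 11.9.

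Within EtOH-160, the group of 4, a single array lay far from the other 3 for 6 of 79 named probe sets and 1 of 9 array measures, where chance gives about 5%; the gap to the nearest array is given as a share of the group's range. Replicate 1 was lowest for Sds (0.85; level 739 against 4394 to 6023) and apart on the second principal component (0.939). Replicate 3 was highest for Igf2r (0.944; 120 against 36.1 to 38.6), H2az1 (0.908; 561 against 448 to 458) and Cpt1a (0.908; 2066 against 793 to 866). Replicate 4 was lowest for Myl12b (0.919; 17.1 against 60.3 to 67.4) and Cat (0.955; 2890 against 3234 to 3252).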

How the results depend on the processing

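The count for ethanol at 160 kcal stayed within 1.5 times of 1168 under every alternative except the values as deposited. Trimmed-mean scaling, the fits without the TEN-160 arrays and the list tests without EtOH-220 replicate 1 were chosen after seeing the data, the other alternatives were planned. Quantile normalization, planned as an alternative, is the main setting and has no separate value. The causes of the changes below were not tested, except that fewer or more probe sets were tested with other filters, other thresholds were set, and the values as deposited keep TEN-220 replicate 1 unscaled.

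Ethanol at 220 kcal (1 call) gave 2 with median-centred values, 58 with the values as deposited, 5 with a pseudocount, 0 with no filter, 8 with the lowest 60% left out, 0 without a trend, 5 with robust eBayes, 16 with array weights, 12 at an adjusted p under 0.10, 0 with only the 2 groups, and 5 without the TEN-160 arrays. Energy with ethanol (15) gave 0 with no filter, 54 at an adjusted p under 0.10 and 6 with only the 2 groups. The values as deposited gave 107 for ethanol at 160 kcal (1168), 346 for energy without ethanol (932), 65 for the interaction (374), 103 for ethanol averaged (500) and 64 for energy averaged (473). At an adjusted p under 0.10 the interaction gave 707, ethanol averaged 849 and energy averaged 763; with array weights the averages gave 792 and 754, and energy averaged gave 313 at 1.5-fold or more.

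Leaving out 1 array gave 0 to 12 for ethanol at 220 kcal, 876 to 1328 for ethanol at 160 kcal, 543 to 1059 for energy without ethanol, 0 to 52 for energy with ethanol, 132 to 344 for the interaction, 296 to 536 for ethanol averaged and 284 to 529 for energy averaged. The lowest of the last 3 and of energy without ethanol came without TEN-220 replicate 1; without replicate 2 these gave 180, 300, 301 and 546, and without EtOH-220 replicate 3 ethanol averaged gave 314. For ethanol at 220 kcal the count was 0 without TEN-220 replicate 1 or 2, EtOH-220 replicate 3 or EtOH-160 replicate 1, 2 or 3, 2 without TEN-160 replicate 1 or 2, 3 without TEN-220 replicate 3 or EtOH-160 replicate 4, 7 without TEN-160 replicate 3 and 12 without EtOH-220 replicate 2. For energy with ethanol it was 0 without EtOH-160 replicate 3 or 4, 5 and 52 without replicates 2 and 1, and 4, 26 and 6 without EtOH-220 replicates 1, 2 and 3.

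With the replicate number as a block, the counts were 2 for ethanol at 220 kcal, 890 for ethanol at 160 kcal, 877 and 2 for energy without and with ethanol, 278 for the interaction, and 324 and 373 for the averages. The numbers do not pair the arrays: deviations of arrays with the same number were correlated at −0.112 to 0.0637 across probe sets.

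Median-centring moved the median change of all probe sets to 0.13 for ethanol at 160 kcal, −0.159 for energy without ethanol and 0.223 for the interaction (0.0154, −0.0287 and 0.0355 before), and the share of calls that were higher to 70.8% (from 53.3%), 24.0% (from 44.1%) and 80.5% (from 56.7%). It moved that share to 86.7% (from 73.3%) for energy with ethanol, 59.7% (from 49.2%) for ethanol averaged and 32.1% (from 46.9%) for energy averaged. Under trimmed-mean scaling these 6 shares were 45.7%, 49.7%, 47.9%, 72.7%, 48.0% and 47.1% in the same order. The values as deposited gave 49.5%, 94.8%, 6.15%, 70.6%, 94.2% and 89.1%, with median changes of all probe sets of 0.702 for energy without ethanol and −0.711 for the interaction; for ethanol at 220 kcal they gave 98.3% and a median of 0.636.

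Lists called numbered 7 for ethanol at 220 kcal, 6 for ethanol at 160 kcal, 1 for energy without ethanol and 7 for energy with ethanol. Each count was 0 with an estimated correlation; with fry they were 0, 7, 3 and 4. Without fry or that correlation they were 6 to 8, 6 to 7, 1 and 5 to 9 in the same order.

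Of the values of named genes under the alternatives, 1 reversed: Cyp2e1 in energy without ethanol, at 0.314 with the values as deposited (adjusted p 0.0104 to 0.665 over its alternatives other than leaving out 1 array). In the same comparison 38 lost and 10 gained a call and 864 did neither; the numbers were 28, 5 and 926 for ethanol at 160 kcal, 9, 46 and 593 for ethanol at 220 kcal, 46, 8 and 590 for energy with ethanol, 31, 10 and 509 for the interaction, 25, 6 and 519 for ethanol averaged and 13, 4 and 533 for energy averaged. Signals near the background of 44 limit the folds of Ptms, Pdpk1, Itga7, Idh1, Alkbh7, Cited2, Hpd, Nr1d1, Nr1d2, Dcn, Afp, Map2k5, Hadh, Socs2, Ank3 and Dbp to lower bounds.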

Other observations

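Some genes separated all ethanol-fed from all ethanol-free rats whatever their energy supply, and these genes were chosen after their values were seen. The signals of 80 of 5244 probe sets did so, 36 higher and 44 lower with ethanol, where chance gives 6.11; another of the 1716 splits of the arrays also gave 80. The steroid-inducible P450 Cyp3a23-3a1 was at 2896 in TEN-220 and 3014 in TEN-160, and at 6869 in EtOH-220 and 10830 in EtOH-160. The flavin monooxygenase Fmo1 and the amino acid oxidase Dao were higher with ethanol by 1.56 and 1.25 on the log2 scale. The differences were −2.36 for Lcn2, which binds bacterial siderophores, −1.22 for the NADPH oxidase subunit Cyba, and −0.89 and −0.73 for the interferon regulators Irf1 and Irf7. Cd14, a coreceptor for endotoxin, was higher on 2 probe sets, by 1.24 and 0.81. Glul, the glutamine synthetase of perivenous cells, was lower by a difference of −0.67.

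All 160 kcal arrays were separated from all 220 kcal arrays by 69 probe sets, 39 higher and 30 lower, where chance gives 6.11 and the highest other split gave 80. Beside Pnpla3, Nr1d2 and Mgll, they included the sulfotransferase Sult1c3 (1.84), the acyl-CoA synthetase Acsm2 (1.43), the carriers Slco1a4 (1.18) and Slc10a1 (0.86) and the urea cycle enzyme Otc (0.69), all higher at 160 kcal, and Tuba4a (−1.22) and Hsph1 (−1.02), both lower.

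Among lists that camera did not call for ethanol at 160 kcal, members often moved in both directions. So did all 5244 tested probe sets, of which 622 were called higher and 546 lower, so this is no trait of these lists. Of 41 cytosolic ribosomal protein genes 6 rose and 11 fell (adjusted p = 0.33), with Rpl17 at 2.04 and Rpl41 at −1.28; of 52 genes of mitochondrial oxidative phosphorylation 5 rose and 4 fell (0.715), with Cox5a at 1.69 and Ndufb11 at −1.27. In the acute phase list 1 of 23 rose and 5 fell (0.302), with Lcn2 at −2.78 and Cd14 at 0.81, though camera called this list under trimmed-mean scaling, and in endoplasmic reticulum stress 2 of 16 rose and 6 fell (0.142), with Canx at −1.13; fry called this list lower (0.0106), and camera called it with the mean of a gene's probe sets. In phase II conjugation 6 of 28 rose and 2 fell (0.407), with Mgst3 at 1.54. Among cell type markers, 3 of 13 genes of stellate cells and fibroblasts fell and 1 rose (0.302), with Col1a1 at −2.29 and Vim at −1.05; 0 of 5 erythroid and 0 of 7 lymphocyte markers were called.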
